A study of Mus musculus with 9 samples.

How the data were processed

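RNA-seq was performed on 9 libraries of cells sorted from lungs of C57BL/6J mice carrying Col1_GFP;Foxf1_tdTomato, 3 libraries per population. Groups and replicate numbers were taken from the sample titles, and each column of the table was matched to its sample through the sequencing core number that the labels give. Per the series design text, ribosomal RNA was depleted with a ribogone step before sequencing. Per the labels' protocols, RNA came from flash-frozen lungs with 1 µg of total RNA put into a TruSeq kit, which is a whole-lung protocol; how that text applies to sorted cells is not stated. Per the submitters' processing notes, reads were trimmed with cutadapt, aligned with TopHat to mm10 and counted with HTSeq, without versions. The strand setting, the annotation and the sort gates are not given in the sources used here, so reads of overlapping or antisense genes, such as Foxf1 and Fendrr with Gm20388, cannot be separated.

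The deposited table holds raw read counts per gene symbol, which the authors made with HTSeq and did not normalise. All values are whole numbers, and the column totals are 17820969 to 26147475. Of its columns, 3 matched no sample and were not used here. The table has 19348 gene symbols, of which 17501 are symbols of the reference annotation (GENCODE M21, RefSeq synonyms), 1702 matched through a unique synonym and 145 did not match. Mitochondrially encoded genes were not measured in the table and are not analysed here. Library depth limits precision for genes of low count; no interval was computed for single libraries, because the spread between replicates was used.

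Genes were kept by edgeR's filterByExpr with its minimum count of 10, which left 15550. A single negative binomial quasi-likelihood model with a mean per population was fitted to all 9 libraries (edgeR 4.0.16, limma 3.58.1, R 4.3.3), with TMM factors, 6 residual degrees of freedom and 3.42 prior degrees of freedom. The 3 pairwise contrasts were tested two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. The standard error of a log2 fold change is its size divided by the square root of the quasi-likelihood F statistic. Genes outside the range of both single-reporter populations were those that passed in both contrasts of DBL with the same sign. Shares of library totals were compared by exact permutation tests.

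The 39 gene lists held 651 entries for 613 genes, covering lung cell types, matrix, signalling pathways, Hox genes, cell state and housekeeping. Of the entries, 622 matched the table and 597 were tested. The 36 lists with at least 4 tested members were tested with camera on log2 CPM (prior count 2) with a preset correlation between genes of 0.01, adjusted over the lists, then with an estimated correlation, and with fry. Fry tests whether the genes of a list move, on balance, in a common direction and compares them with no other genes. Beside each list stands the number of members passing over all genes and adjusted over the list alone. Several lists share genes: Hhip is in the smooth muscle and lung mesenchyme lists, and Tbx2 in the aerocyte and lung mesenchyme lists.

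The named genes of each comparison were the sort genes Foxf1, Col1a1 and Col1a2, the 8 genes with the largest log2 fold change in each direction, and up to 4 members of each list described, by adjusted p. The 8 had to pass the test, reach 10 CPM in the higher group and not overlap between groups; unnamed gene models, 74, 148 and 241 of the genes that met these terms, were left out. Some genes that met the rule are not reported here. For genes outside the range, the 10 with the largest smaller change were named in each direction, at 10 CPM or more. The groups, comparisons, tests, gene lists, rule for named genes and the other choices compared below were fixed before the data were examined. The transcripts of the Dlk1-Dio3 locus, the surfactant transcripts and the fit to the 6 libraries of the second series were chosen after the values had been seen.

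These choices were DESeq2 size factors, library totals or upper-quartile factors for scaling, DESeq2 1.42.0, limma-voom, no filter, a filter of 10 CPM in 3 libraries, a test against a log2 fold change of 1, only the 2 groups compared, the replicate number as a block, 2 groupings of core numbers as covariates, leaving out the 20 most abundant genes, and leaving out each library. In simulated data of the same size, 73% of 100 genes changed 2-fold and 99% of 100 changed 4-fold were recovered. There were 6 false calls among 15324 genes. In simulation camera called only the 1 shifted list. False calls under a shift of the replicate 1 libraries, and list calls at real correlations between genes (endothelium 0.515), were not gauged. A simulated mixture with 30% TDonly was recovered as 30.5%. Mixture weights, predicted levels and level ratios used CPM of library totals, without TMM factors.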

Results

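RNA-seq read counts per gene were obtained for 9 libraries of sorted lung cells from C57BL/6J mice carrying Col1_GFP;Foxf1_tdTomato, a green reporter of type I collagen and a red reporter of Foxf1. Foxf1 is a forkhead transcription factor of the lung mesenchyme and endothelium. The cells formed 3 populations with 3 libraries each. DBL cells carried both reporters (replicates 1, 3 and 4), ColGFP cells carried the collagen reporter alone (replicates 1, 2 and 3) and TDonly cells carried the Foxf1 reporter alone (replicates 1, 2 and 3). Total counts were 26147475, 22141810 and 25408917 in the DBL libraries, 22249779, 17820969 and 23376574 in ColGFP and 25715957, 23151867 and 20765519 in TDonly. Between 17116 and 17753 genes per library had at least 1 count, and 15550 genes passed the filter on low counts. Levels are CPM (counts scaled to library size) with TMM factors, given as mean ± SD (n = 3 per population). Log2 fold changes are given with their standard errors.

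The ribosomal RNA precursor Rn45s took 2.77 to 7.90% of the counts of a library. The 10 most abundant other genes took 9.50 ± 0.564% in DBL, 9.93 ± 1.39% in ColGFP and 6.49 ± 0.341% in TDonly (SD, n = 3). None of 12 comparisons of such shares passed the threshold by exact two-sided permutation tests, whose smallest possible p with 3 against 3 is 0.1; the smallest adjusted p was 0.6. The first principal component held 64.1% of the variance and placed DBL between ColGFP and TDonly. In each population, replicate 1 stood apart. Chi-square per degree of freedom across genes was 57.0 to 104 for pairs with replicate 1, and 5.51 in ColGFP, 15.3 in DBL and 8.66 in TDonly for the other pair. The replicate 1 libraries have sequencing core numbers of a lower series and the others have numbers of a higher one (the second series), which no label calls a batch. Nothing in the labels says that replicates come from separate animals, so the p-values measure the spread between samples, which may be technical.

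**Figure D1:**
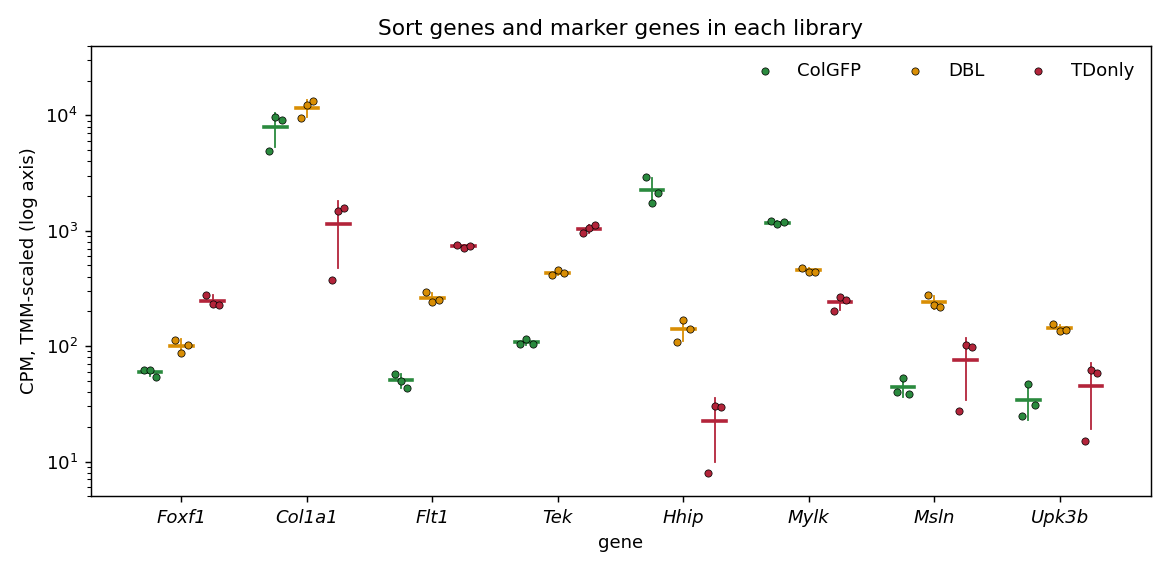
Levels of sort genes and markers in each library, in TMM-scaled CPM on a log axis, for ColGFP (green), DBL (orange) and TDonly (red). Points are libraries, horizontal bars are means and vertical lines are 1 SD (n = 3); Foxf1, Flt1 and Tek lie between the other populations in DBL, whereas Msln and Upk3b are highest there.

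The comparison of DBL with ColGFP asked which transcripts distinguish collagen reporter cells that also carry the Foxf1 reporter, the subject of the series title. Foxf1 (Foxf1a in the file; mm10 chromosome 8, 121084386 to 121088144, plus strand) measured 101 ± 13.1 CPM in DBL and 59.7 ± 4.47 in ColGFP (log2 fold change 0.76 ± 0.13, adjusted p = 0.00329). Fendrr, a long non-coding RNA transcribed from the opposite strand beside Foxf1 (121054882 to 121083110), measured 97.8 ± 37.3 CPM in DBL and 32.6 ± 1.55 in ColGFP (log2 fold change 1.59 ± 0.33, adjusted p = 0.01001). The gene model Gm20388 overlaps both genes, so their counts could hold reads of either strand. Among the 10 genes of the list of the Foxf1 locus and forkhead partners, 3 were higher and 1 lower, with the same counts adjusted over the list alone and 6 and 1 within the second series (camera adjusted p = 0.0312 with the preset correlation and adjusted p = 0.219 with an estimated correlation). The lower one was Foxf2, the closest paralog of Foxf1, at 24.7 ± 0.301 against 77.4 ± 3.04 CPM (log2 fold change -1.65 ± 0.26). Foxp1 was higher, at log2 0.68 ± 0.10. Within the second series alone the log2 fold change of Foxf1 was 0.72 (adjusted p = 7.86e-06), and between the replicate 1 libraries it was 0.87. The type I collagen genes that define the green sort, Col1a1 (chromosome 11, 94936224 to 94953042) and Col1a2 (chromosome 6, 4504814 to 4541544), did not pass the test. Col1a1 measured 11668 ± 1908 CPM in DBL and 7904 ± 2577 in ColGFP (log2 fold change 0.56 ± 0.47, adjusted p = 0.509) and Col1a2 measured 8925 ± 1299 CPM in DBL and 6419 ± 2137 in ColGFP (log2 fold change 0.48 ± 0.46, adjusted p = 0.573). Within the second series, a fit chosen after the data were seen, Col1a1 was higher in DBL by 0.45 on the log2 scale (adjusted p = 1.28e-05) and Col1a2 by 0.35 (adjusted p = 0.000114).

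Endothelial transcripts were higher in DBL than in ColGFP. All 23 genes of the endothelium list passed, and all 23 adjusted over the list alone, with a median log2 fold change of 2.38 (camera adjusted p = 2.54e-29 with the preset correlation and adjusted p = 0.157 with an estimated correlation). Flt1, a receptor for VEGF, measured 262 ± 27.6 CPM in DBL and 50.4 ± 7.16 in ColGFP (log2 fold change 2.38 ± 0.13, adjusted p = 1.03e-05). The angiopoietin receptor Tek, the adrenomedullin receptor subunit Ramp2 and the adhesion molecule Icam2 were higher by 2.01 ± 0.11, 2.21 ± 0.11 and 2.33 ± 0.12 (log2). Of the 12 general capillary genes, 11 were higher, and all 12 adjusted over the list alone (camera adjusted p = 1.54e-13, and adjusted p = 0.136 with an estimated correlation); Kit measured 242 ± 8.49 against 67.6 ± 13.2 CPM and the receptor for apelin, Aplnr, 95.2 ± 8.10 against 17.3 ± 4.76. Of the 12 aerocyte capillary genes, 6 were higher and 1 lower (6 and 1 adjusted over the list alone), with camera adjusted p = 0.000797, and adjusted p = 0.219 with an estimated correlation. Its higher members Prx and Car4 changed by 1.97 ± 0.12 and 1.91 ± 0.14, and its lower member was Tbx2, a T-box factor also made by lung fibroblasts. In the VEGF, angiopoietin and Notch list of 21 genes, 10 were higher and 2 lower (11 and 6 adjusted over the list alone). Among them Dll4 and Notch4, a Notch ligand and receptor of endothelium, were higher by 2.27 ± 0.12 and 2.38 ± 0.18 (camera adjusted p = 0.00440, and adjusted p = 0.157 with an estimated correlation). The lower count of this list was 0 without ColGFP replicate 2, 1 without DBL replicate 1, 3 or 4, ColGFP replicate 1 or 3, or TDonly replicate 3, and 6 without TDonly replicate 1. It was 8 within the second series.

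Many transcripts of alveolar fibroblasts and smooth muscle were lower in DBL. Of 18 alveolar fibroblast and lipofibroblast genes, 13 were lower and none higher, and 16 were lower adjusted over the list alone (median log2 fold change -1.54; camera adjusted p = 5.17e-08 with the preset correlation and adjusted p = 0.450 with an estimated correlation). Macf1, a cytoskeletal crosslinker, measured 2989.7 ± 201 CPM in DBL and 9173 ± 718 in ColGFP (log2 fold change -1.62 ± 0.16, adjusted p = 0.000156); Limch1 and the glycogen primer Gyg were lower at -1.56 ± 0.20 and -1.52 ± 0.24. The count of lower alveolar fibroblast genes was 8 without DBL replicate 3, DBL replicate 4, ColGFP replicate 2 or ColGFP replicate 3. Of 17 smooth muscle and myofibroblast genes, 8 were lower, 14 adjusted over the list alone and 15 within the second series (camera adjusted p = 5.17e-08 with the preset correlation and adjusted p = 0.326 with an estimated correlation). Myosin light chain kinase Mylk was at 455 ± 22.0 against 1175 ± 34.2 CPM, and Myocd, the transcriptional coactivator of smooth muscle genes, at 10.2 ± 0.944 against 36.5 ± 8.29. The hedgehog antagonist Hhip, a member of this list and of the lung mesenchyme list, measured 139 ± 29.7 CPM in DBL and 2275 ± 611 in ColGFP (log2 fold change -4.03 ± 0.47, adjusted p = 0.000468). Of the 14 lung mesenchyme transcription factor and hedgehog genes, 1 was higher and 4 lower (1 and 4 adjusted over the list alone), with camera adjusted p = 0.123. Tbx2 and Tbx4 were lower at -1.47 ± 0.10 and -1.92 ± 0.33 and Tbx3 higher at 0.85 ± 0.08. Immediate early and heat shock genes, induced by tissue dissociation, had 1 lower member of 20, also adjusted over the list alone, Dusp1 at -0.53 ± 0.13 (camera adjusted p = 0.00877, and adjusted p = 0.683 with an estimated correlation). Dusp1 missed the threshold without DBL replicate 1 or 3 or ColGFP replicate 2 or 3 (adjusted p 0.0630 to 0.0812). The count of lower immediate early genes was 0 without DBL replicate 1 or 3 or ColGFP replicate 2 or 3, 3 without TDonly replicate 1, and 4 without ColGFP replicate 1. It was 13 within the second series.

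Some signalling genes were higher and others lower. Of 17 FGF and HGF ligands and receptors, 8 were lower, with 1 higher and 10 lower adjusted over the list alone (camera adjusted p = 0.000716 with the preset correlation and adjusted p = 0.157 with an estimated correlation). The feedback inhibitor Spry1, hepatocyte growth factor Hgf and the receptor Fgfr3 were lower at -1.26 ± 0.14, -1.06 ± 0.13 and -1.06 ± 0.14. The count was 5 without DBL replicate 1 and 4 without DBL replicate 3, DBL replicate 4, ColGFP replicate 2 or ColGFP replicate 3. Of 22 WNT pathway genes, 2 were higher and 6 lower (5 and 6 adjusted over the list alone), with camera adjusted p = 0.166. The WNT target Axin2 and the R-spondin receptors Lgr5 and Lgr6 were lower at -1.32 ± 0.15, -2.74 ± 0.33 and -3.87 ± 0.47. In the second series 4 were higher and 10 lower. The higher WNT count was 0 without DBL replicate 1, 3 or 4 or ColGFP replicate 2 or 3. Of 24 BMP and TGF-beta genes, 7 were higher and 10 lower (7 and 11 adjusted over the list alone), with camera adjusted p = 0.395. They included the endothelial BMP receptor Acvrl1 at 1.73 ± 0.10 and the BMP target Smad6 at 1.67 ± 0.10. Of 14 anterior Hox genes, 8 were lower, 10 adjusted over the list alone; Hoxa5, which patterns lung mesenchyme, measured 41.4 ± 7.64 against 89.4 ± 7.10 CPM (camera adjusted p = 3.27e-06 with the preset correlation and adjusted p = 0.157 with an estimated correlation). Without DBL replicate 1, DBL replicate 3 or ColGFP replicate 2 the Hox count was 4, and without DBL replicate 4 or ColGFP replicate 3 it was 5. Enpp2, the enzyme that makes lysophosphatidic acid, measured 72.1 ± 5.08 CPM in DBL and 623 ± 91.3 in ColGFP (log2 fold change -3.11 ± 0.16, adjusted p = 1.03e-05), and the matrix glycoprotein Thbs1 2192 ± 192 CPM in DBL and 11923 ± 2689 in ColGFP (log2 fold change -2.44 ± 0.24, adjusted p = 0.000175).

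Some mesothelial and adventitial genes were higher in DBL than in ColGFP. Of 9 mesothelium genes measured, 6 were higher and 7 adjusted over the list alone (camera adjusted p = 0.00137 with the preset correlation and adjusted p = 0.591 with an estimated correlation). Mesothelin, Msln, measured 241 ± 32.2 CPM in DBL and 43.9 ± 7.56 in ColGFP (log2 fold change 2.46 ± 0.41, adjusted p = 0.00356), and the glycoprotein Gpm6a 87.7 ± 13.7 CPM in DBL and 21.6 ± 7.28 in ColGFP (log2 fold change 2.03 ± 0.41, adjusted p = 0.00904). Bnc1 and uroplakin Upk3b were higher at 2.19 ± 0.47 and 2.07 ± 0.45. Bnc1 missed the threshold without ColGFP replicate 2 (adjusted p = 0.0525), Upk3b without ColGFP replicate 3 (adjusted p = 0.0639), and the count of higher mesothelium genes was 3 without ColGFP replicate 3. Of 21 adventitial fibroblast genes, 8 were higher, 9 adjusted over the list alone and 15 within the second series, where 1 was lower (camera adjusted p = 0.000202 with the preset correlation and adjusted p = 0.560 with an estimated correlation). They included the alarmin Il33 at 1.57 ± 0.17 and Dpp4 at 1.38 ± 0.20. Ly6a and Ly6c1, at 2.32 ± 0.32 and 2.59 ± 0.32, are also expressed by endothelium. The adventitial count was 5 without DBL replicate 1, DBL replicate 3 or ColGFP replicate 3, and 4 without DBL replicate 4. Of 25 chemokine and cytokine genes, 9 were higher and 1 lower (9 and 2 adjusted over the list alone), with camera adjusted p = 0.0107 with the preset correlation and adjusted p = 0.560 with an estimated correlation. They included Cxcl12 at 1.79 ± 0.27 and Cx3cl1 at 1.51 ± 0.18. The count of higher chemokine genes was 4 without DBL replicate 1, ColGFP replicate 2 or ColGFP replicate 3, and 5 without ColGFP replicate 1 or TDonly replicate 2.

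Markers of cells outside the reporters were measured beside these groups. Of 20 epithelium genes, only Krt19 was higher in DBL, at 1.10 ± 0.28, and none passed adjusted over the list alone (camera adjusted p = 0.0193 with the preset correlation and adjusted p = 0.695 with an estimated correlation). By edgeR, 5 epithelium genes were higher at an unadjusted p under 0.05. Krt19 missed the threshold without DBL replicate 3 or 4 or ColGFP replicate 2 or 3 (adjusted p 0.0668 to 0.102). The count of higher epithelium genes was 0 without DBL replicate 3 or 4 or ColGFP replicate 2 or 3, and 13 without ColGFP replicate 1. Within the second series all 20 epithelium genes were higher in DBL, with a median log2 fold change of 0.84. None of 20 leukocyte genes passed by edgeR, with 0 higher and 0 lower at an unadjusted p under 0.05 (camera adjusted p = 0.0774); within the second series 3 were higher and 2 lower. None of 11 housekeeping genes passed by edgeR, with 1 higher at an unadjusted p under 0.05.

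The 8 named genes with the largest higher values in DBL included endothelial transcripts. Selp and Sele, the P- and E-selectins that tether leukocytes, were higher at 3.59 ± 0.73 and 3.55 ± 0.77, and Edn1, the endothelin precursor, at 3.01 ± 0.63. The endothelial transcription factor Sox17 measured 57.9 ± 12.3 CPM in DBL and 8.09 ± 1.43 in ColGFP (log2 fold change 2.84 ± 0.23, adjusted p = 5.94e-05), and Grrp1 and Mctp1 were higher at 2.92 ± 0.30 and 2.88 ± 0.46. The B-cell chemokine Cxcl13 and the neural adhesion molecule Chl1 were higher at 3.25 ± 0.94 and 3.59 ± 1.00. DBL replicate 1 was the highest of these libraries for Selp (52.8 CPM against 12.9 and 11.1 in replicates 3 and 4), Sele (23.6 against 5.41 and 6.02), Edn1 (106 against 29.3 and 26.8), Cxcl13 (79.7 against 5.99 and 6.22) and Chl1 (55.0 against 5.54 and 4.16). Without DBL replicate 1 the log2 fold changes of Chl1 and Cxcl13 were 1.43 (adjusted p = 0.123) and 0.92 (adjusted p = 0.0547). Chl1 and Cxcl13 missed the threshold without DBL replicate 1, ColGFP replicate 1, 2 or 3, or TDonly replicate 2 or 3 (adjusted p 0.0565 to 0.143 and 0.0547 to 0.146). Sele did so without ColGFP replicate 3 (adjusted p = 0.0611) and Edn1 without ColGFP replicate 2 (adjusted p = 0.0524). By limma-voom none of Selp, Sele, Edn1, Cxcl13 and Chl1 passed (adjusted p = 0.112, 0.141, 0.0544, 0.301 and 0.270). The largest lower values included those of Hhip, Lgr6, Fhod3, Trim67, Cyp2e1, Gpr30 and Cdh4. Fhod3, an actin-assembling formin, changed by -3.78 ± 0.32; the cytochrome P450 Cyp2e1 by -3.47 ± 0.13; and R-cadherin Cdh4 by -3.36 ± 0.18. Trim67 changed by -3.57 ± 0.46 and Gpr30, now Gper1, a membrane oestrogen receptor, by -3.39 ± 0.49.

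By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2256 genes differed between DBL and ColGFP, 1250 higher and 1006 lower in DBL. Of these, 724 were at least 2-fold higher and 440 at least 2-fold lower, and 4186 genes had an unadjusted p under 0.05. The libraries of both populations did not overlap for 33.3% of genes, where chance gives 10%. Camera called 18 of 36 lists with its preset correlation and 0 with an estimated one, where 8 had an unadjusted p under 0.05; fry called 16. The count of differing genes was 1478 without ColGFP replicate 2 and 1468 without ColGFP replicate 3. The count of lower genes was 669, 660 and 581 without DBL replicates 1, 3 and 4, and 617 and 623 without ColGFP replicates 2 and 3. Within the second series 4512 genes differed, 2193 of them shared with the 2256, and with the replicate number as a block 626 were lower. Scaling by library totals alone moved the share of differing genes that were higher from 55.4% to 64.8%.

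**Figure D2:**
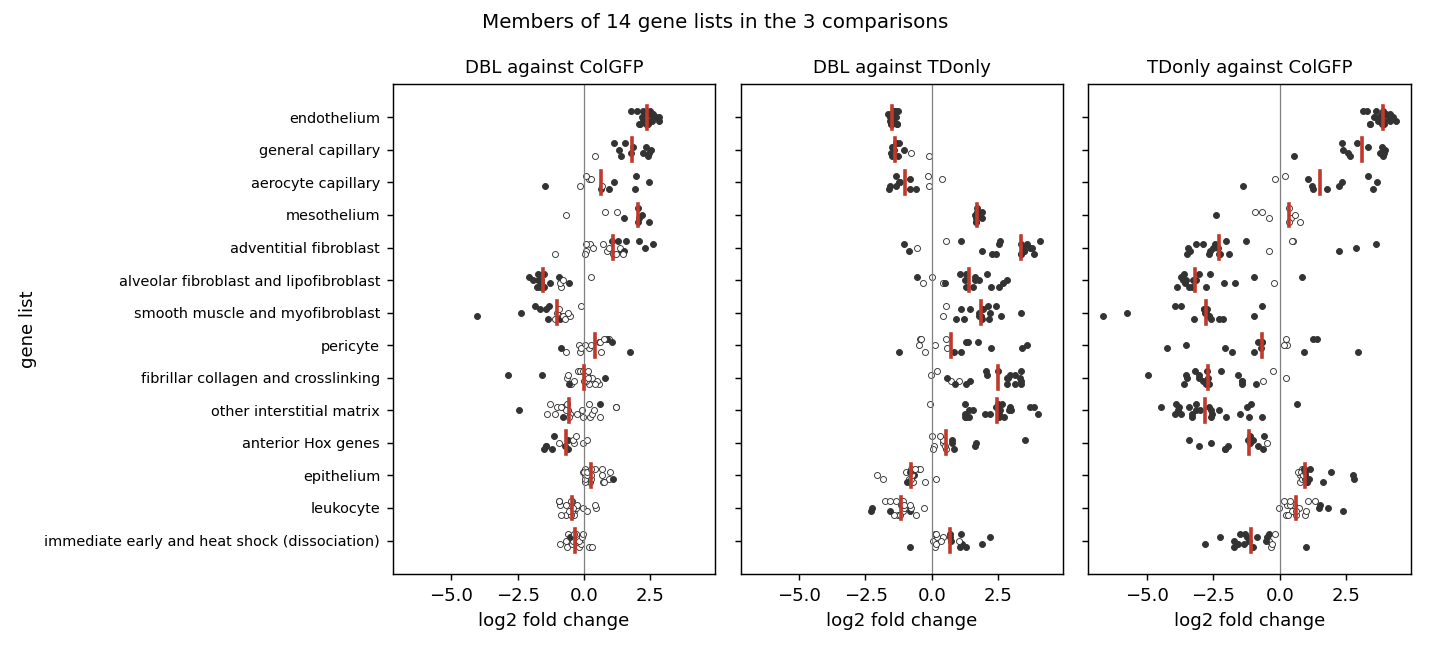
Log2 fold changes (x axis) of the measured members of gene lists fixed in advance (y axis) in each of the 3 comparisons. Filled points passed the test (adjusted p under 0.05 over all genes), open points did not, and red bars are list medians; endothelium genes lie at a median of 2.38 in DBL against ColGFP and of -1.49 in DBL against TDonly.

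The comparison of DBL with TDonly set Foxf1 reporter cells with the collagen reporter against those without it. Collagen and matrix transcripts were higher in DBL and endothelial transcripts lower. Col1a1 measured 11668 ± 1908 CPM in DBL and 1144 ± 669 in TDonly (log2 fold change 3.35 ± 0.52, adjusted p = 0.00103), Col1a2 8925 ± 1299 CPM in DBL and 867 ± 494 in TDonly (log2 fold change 3.36 ± 0.50, adjusted p = 0.000873) and Foxf1 101 ± 13.1 CPM in DBL and 246 ± 28.5 in TDonly (log2 fold change -1.28 ± 0.13, adjusted p = 0.000123). Within the second series the log2 fold changes were 3.10 for Col1a1 and -1.23 for Foxf1, and between the replicate 1 libraries 4.68 and -1.29. Of 21 fibrillar collagen and crosslinking genes, 17 were higher and none lower, with 18 higher adjusted over the list alone (camera adjusted p = 2.90e-10 with the preset correlation and adjusted p = 0.309 with an estimated correlation). Col5a2 measured 833 ± 52.5 CPM in DBL and 146 ± 39.0 in TDonly (log2 fold change 2.51 ± 0.22, adjusted p = 8.29e-05), and the lysyl oxidases Loxl2 and Loxl3 and the collagen chaperone Serpinh1 were higher at 2.05 ± 0.18, 2.83 ± 0.26 and 1.44 ± 0.16. Of 24 genes of other interstitial matrix, 23 were higher, the same count as adjusted over the list alone (camera adjusted p = 2.60e-13 with the preset correlation and adjusted p = 0.309 with an estimated correlation). The proteoglycans Vcan, Bgn and Lum were higher at 2.98 ± 0.17, 2.56 ± 0.25 and 4.01 ± 0.41. All 23 endothelium genes were lower, also adjusted over the list alone (median log2 fold change -1.49; camera adjusted p = 1.47e-14 with the preset correlation and adjusted p = 0.309 with an estimated correlation). Tek was at 434 ± 18.7 against 1044 ± 87.6 CPM and Flt1 at 262 ± 27.6 against 732 ± 20.6. Of 12 general capillary genes, 10 were lower and 11 adjusted over the list alone (camera adjusted p = 2.23e-07, and adjusted p = 0.309 with an estimated correlation), among them Kit at -1.48 ± 0.13 and Glp1r at -1.53 ± 0.14. Of 12 aerocyte genes, 9 were lower on either adjustment, among them Car4 at -1.60 ± 0.13 (camera adjusted p = 0.000102, and adjusted p = 0.309 with an estimated correlation).

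Most fibroblast, smooth muscle and mesothelial genes were higher in DBL than in TDonly. Of 18 alveolar fibroblast genes, 14 were higher and 1 lower (14 and 1 adjusted over the list alone), with camera adjusted p = 0.000123 with the preset correlation and adjusted p = 0.445 with an estimated correlation. The receptor Pdgfra measured 1065 ± 109 CPM in DBL and 168 ± 93.1 in TDonly (log2 fold change 2.67 ± 0.41, adjusted p = 0.00104) and the transcription factor Tcf21 was higher at 2.54 ± 0.35. The count of higher alveolar fibroblast genes was 9 without DBL replicate 3. Of 17 smooth muscle genes, 15 were higher and all 17 adjusted over the list alone, among them Myl9 at 1.89 ± 0.25 (camera adjusted p = 1.10e-08, and adjusted p = 0.315 with an estimated correlation). Of 21 adventitial genes, 17 were higher and 2 lower (18 and 2 adjusted over the list alone), with camera adjusted p = 2.96e-06 with the preset correlation and adjusted p = 0.401 with an estimated correlation. They included Dpt and Mfap5, proteins of loose connective tissue, at 3.38 ± 0.46 and 3.46 ± 0.52. All 9 mesothelium genes were higher, also adjusted over the list alone; Rspo1 was at 1.90 ± 0.40 and Upk1b at 1.73 ± 0.36 (camera adjusted p = 0.000369, and adjusted p = 0.437 with an estimated correlation). Of the 14 lung mesenchyme and hedgehog genes, 12 were higher and 1 lower (12 and 1 adjusted over the list alone), with camera adjusted p = 8.50e-06 with the preset correlation and adjusted p = 0.401 with an estimated correlation. The hedgehog effectors Gli1 and Gli3 were higher at 3.39 ± 0.37 and 2.12 ± 0.13, and Tbx3 lower at -1.37 ± 0.09. Of 22 WNT genes, 14 were higher and 2 lower (15 and 2 adjusted over the list alone), with camera adjusted p = 7.98e-05, and adjusted p = 0.433 with an estimated correlation. Wnt5a was at 3.27 ± 0.38 and Sfrp1 at 2.89 ± 0.24. Of 25 chemokine genes, 14 were higher and 2 lower (14 and 3 adjusted over the list alone), with camera adjusted p = 0.00357, and adjusted p = 0.407 with an estimated correlation. Cxcl1 was at 3.69 ± 0.54. Of 14 anterior Hox genes, 6 were higher on either adjustment, with Hoxb3 at 0.77 ± 0.14 (camera adjusted p = 0.000614, and adjusted p = 0.315 with an estimated correlation). Of 17 FGF and HGF genes, 9 were higher and 3 lower (10 and 5 adjusted over the list alone), with camera adjusted p = 0.0446, and adjusted p = 0.339 with an estimated correlation. Fgfr1 was at 2.73 ± 0.23 and Fgf7 at 2.65 ± 0.41. The lower FGF and HGF count was 1 without DBL replicate 3 or 4, and 5 without ColGFP replicate 1.

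Immediate early, leukocyte and epithelial genes were counted between DBL and TDonly. Of 20 immediate early and heat shock genes, 10 were higher and 1 lower (10 and 1 adjusted over the list alone), with camera adjusted p = 0.000614 with the preset correlation and adjusted p = 0.462 with an estimated correlation; within the second series 16 were higher. Nr4a1 and Fosb were higher at 1.88 ± 0.30 and 1.15 ± 0.20. Of 20 leukocyte genes, 5 were lower and 9 adjusted over the list alone (camera adjusted p = 0.000614 with the preset correlation and adjusted p = 0.445 with an estimated correlation). The macrophage chitinase-like gene Chi3l3 (now Chil3) was lower at -2.24 ± 0.41. The leukocyte count was 9 without TDonly replicate 1, 2 without TDonly replicate 2, 1 without TDonly replicate 3 or DBL replicate 3, and 18 within the second series. Of 20 epithelium genes, 3 were lower and none adjusted over the list alone, with 12 lower at an unadjusted p under 0.05 by edgeR (camera adjusted p = 0.00248 with the preset correlation and adjusted p = 0.560 with an estimated correlation). They were Muc1, Abca3 and Hopx at -0.82 ± 0.25, -0.67 ± 0.21 and -0.94 ± 0.30. The count of lower epithelium genes was 0 without DBL replicate 1, 3 or 4 or TDonly replicate 2 or 3, 7 without ColGFP replicate 3, and 15 without ColGFP replicate 1. It was 19 within the second series. Muc1 missed the threshold without DBL replicate 1, 3 or 4 or TDonly replicate 1, 2 or 3 (adjusted p 0.0642 to 0.0978), Abca3 without DBL replicate 1, 3 or 4, TDonly replicate 1, 2 or 3, or ColGFP replicate 2 (adjusted p 0.0635 to 0.104) and Hopx without DBL replicate 1, 3 or 4 or TDonly replicate 2 or 3 (adjusted p 0.0837 to 0.118).

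The largest higher values in DBL against TDonly were those of Ptx3, Penk, Ccl11, Kcnt2, Ccl7, Lum, Lsamp and Zcchc5 (now Rtl3), with log2 fold changes from 3.97 to 4.17. The pentraxin Ptx3 measured 45.9 ± 25.99 CPM in DBL and 2.56 ± 0.257 in TDonly (log2 fold change 4.17 ± 0.78, adjusted p = 0.00297), the opioid precursor Penk 51.4 ± 11.9 CPM in DBL and 2.93 ± 1.95 in TDonly (log2 fold change 4.14 ± 0.60, adjusted p = 0.000792) and the eosinophil chemokine Ccl11 98.8 ± 8.47 CPM in DBL and 5.82 ± 3.62 in TDonly (log2 fold change 4.09 ± 0.65, adjusted p = 0.00125). Ccl7, a monocyte chemokine, was higher at 4.05 ± 0.56. The largest lower values included the airway secretory genes Bpifa1, Muc5b and Bpifb1 at -2.30 ± 0.77, -2.28 ± 0.69 and -2.25 ± 0.72. Macrophage-expressed Chi3l3, Ccl6, Mrc1 and Ctss were also among them, at -2.24 ± 0.41, -2.12 ± 0.59, -2.05 ± 0.54 and -1.87 ± 0.51, and Cytl1 was lower at -2.02 ± 0.22. Bpifa1 missed the threshold without DBL replicate 1, 3 or 4, ColGFP replicate 2, or TDonly replicate 2 or 3 (adjusted p 0.0650 to 0.123). Muc5b and Bpifb1 did so without DBL replicate 1, 3 or 4 or TDonly replicate 2 or 3 (adjusted p 0.0680 to 0.0881 and 0.0860 to 0.105). Ccl6 did so without TDonly replicate 2 or 3 (adjusted p 0.0569 to 0.0805), Mrc1 without DBL replicate 3 or TDonly replicate 3 (adjusted p 0.0549 to 0.0660) and Ctss without TDonly replicate 2 or 3 (adjusted p 0.0522 to 0.0730).

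In all, 4657 genes differed between DBL and TDonly by the same test, 2692 higher and 1965 lower in DBL, with 1675 and 701 of them at least 2-fold higher and lower. An unadjusted p under 0.05 was met by 6331 genes, and 47.0% of genes had no overlap between the populations (chance 10%). Camera called 22 of 36 lists with the preset correlation and 0 with an estimated one, where 5 had an unadjusted p under 0.05; fry called 24. The count of lower genes was 1155 without DBL replicate 4 and 3031 within the second series. Scaling by library totals alone turned the balance, with 2309 higher and 2454 lower in DBL (48.5% of differing genes higher, against 57.8%).

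The comparison of TDonly with ColGFP set the single-reporter populations against each other. TDonly cells carried the most endothelial transcripts. All 23 endothelium genes were higher than in ColGFP, also adjusted over the list alone (median log2 fold change 3.89; camera adjusted p = 1.84e-18 with the preset correlation and adjusted p = 0.255 with an estimated correlation). Tek measured 1044 ± 87.6 CPM in TDonly and 108 ± 6.14 in ColGFP (log2 fold change 3.28 ± 0.11, adjusted p = 1.67e-07), and Icam2 and Ramp2 were higher at 3.86 ± 0.13 and 3.64 ± 0.12. All 12 general capillary genes were higher, among them Ptprb, a phosphatase of the endothelial membrane, at 4796 ± 60.6 against 331 ± 79.6 CPM (camera adjusted p = 2.34e-09, and adjusted p = 0.255 with an estimated correlation). Of 12 aerocyte genes, 9 were higher and 1 lower (9 and 1 adjusted over the list alone), with camera adjusted p = 0.000290, and adjusted p = 0.304 with an estimated correlation. Prx was at 3.32 ± 0.13. Foxf1 measured 246 ± 28.5 CPM in TDonly and 59.7 ± 4.47 in ColGFP (log2 fold change 2.05 ± 0.13, adjusted p = 2.22e-06), with 1.95 within the second series and 2.16 between the replicate 1 libraries, and Fendrr was higher at 2.63 ± 0.34. Foxf2 was lower at -3.19 ± 0.28; of the 10 genes of that list 4 were higher and 3 lower (4 and 4 adjusted over the list alone) (camera adjusted p = 0.702). Col1a1 measured 1144 ± 669 CPM in TDonly and 7904 ± 2577 in ColGFP (log2 fold change -2.79 ± 0.50, adjusted p = 0.00145), with -2.64 and -3.74 in the same order. Of 21 fibrillar collagen genes, 18 were lower and 19 adjusted over the list alone, with P4ha3, a prolyl hydroxylase subunit, at -4.96 ± 0.33 (camera adjusted p = 1.32e-07 with the preset correlation and adjusted p = 0.351 with an estimated correlation). Of 24 other matrix genes, 23 were lower and 1 higher on either adjustment, with Thbs1 at -3.84 ± 0.26 (camera adjusted p = 2.34e-09, and adjusted p = 0.351 with an estimated correlation).

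All 17 smooth muscle genes were lower in TDonly than in ColGFP, also adjusted over the list alone (camera adjusted p = 4.26e-09 with the preset correlation and adjusted p = 0.351 with an estimated correlation). Mylk was at 239 ± 34.8 against 1175 ± 34.2 CPM. Of 18 alveolar fibroblast genes, 1 was higher and 16 lower (1 and 16 adjusted over the list alone), with camera adjusted p = 9.17e-07, and adjusted p = 0.417 with an estimated correlation. Macf1 was at -2.10 ± 0.16. Of 21 adventitial genes, 3 were higher and 15 lower (4 and 15 adjusted over the list alone), with camera adjusted p = 0.0602. Pcolce2 was lower at -3.49 ± 0.45 and Ly6c1 higher at 3.63 ± 0.34. Of 14 anterior Hox genes, 13 were lower and 14 adjusted over the list alone, with Hoxb6 at -3.04 ± 0.28 (camera adjusted p = 3.95e-06, and adjusted p = 0.255 with an estimated correlation). Of 14 lung mesenchyme and hedgehog genes, 1 was higher and 13 lower (1 and 13 adjusted over the list alone), with camera adjusted p = 9.13e-06, and adjusted p = 0.351 with an estimated correlation. Tbx3 was the higher one, at 2.22 ± 0.09. Of 9 mesothelium genes, only Upk1b passed, lower at -2.41 ± 0.37, also adjusted over the list alone (camera adjusted p = 0.617). Without TDonly replicate 1, 5 mesothelium genes were higher, and within the second series 5 were higher and 4 lower. Msln was then at 1.11 (adjusted p = 9.43e-08), against -0.57 between the replicate 1 libraries. Of 22 WNT genes, 2 were higher and 14 lower (2 and 14 adjusted over the list alone), with camera adjusted p = 0.000241, and adjusted p = 0.492 with an estimated correlation. Lgr5 was at -4.49 ± 0.38. Of 17 FGF and HGF genes, 2 were higher and 12 lower (3 and 12 adjusted over the list alone), with camera adjusted p = 0.00364, and adjusted p = 0.255 with an estimated correlation. Fgf2 was at -3.17 ± 0.29. The higher FGF and HGF count was 5 without ColGFP replicate 1. Of 24 BMP and TGF-beta genes, 7 were higher and 15 lower (7 and 15 adjusted over the list alone), with camera adjusted p = 0.0958. Bmp6 was higher at 3.97 ± 0.19. Of 21 VEGF and Notch genes, 10 were higher and 9 lower (10 and 9 adjusted over the list alone), with camera adjusted p = 0.308. Dll4 was higher at 3.62 ± 0.13.

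Markers of other cells were counted as well. Of 20 epithelium genes, 12 were higher in TDonly, 17 adjusted over the list alone and 20 within the second series (camera adjusted p = 0.000213 with the preset correlation and adjusted p = 0.555 with an estimated correlation). Hopx and Abca3, genes of the alveolar epithelium, were higher at 1.65 ± 0.30 and 0.94 ± 0.21. The epithelium count was 20 without ColGFP replicate 1, 4 and 6 without ColGFP replicates 2 and 3, and 5 without TDonly replicate 2 or 3. Of 20 leukocyte genes, 4 were higher, 3 adjusted over the list alone, 9 without TDonly replicate 1 and 17 within the second series (camera adjusted p = 0.102); Cd74 was at 1.502 ± 0.379. Of 20 immediate early and heat shock genes, 1 was higher and 15 lower (1 and 15 adjusted over the list alone), with camera adjusted p = 0.000221 with the preset correlation and adjusted p = 0.555 with an estimated correlation. Fos was at -1.71 ± 0.21 and Nr4a1 at -2.80 ± 0.31. The count of lower immediate early genes was 9 without ColGFP replicate 2.

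The largest higher values in TDonly against ColGFP were those of Ido1, Selp, Sele, Pydc4 (now Ifi213), Tgtp1, Edn1, Clec12b and Sox17, with log2 fold changes from 4.38 to 5.93. Sox17 measured 168 ± 43.2 CPM in TDonly and 8.09 ± 1.43 in ColGFP (log2 fold change 4.38 ± 0.24, adjusted p = 1.04e-06) and Selp 62.2 ± 40.2 CPM in TDonly and 2.09 ± 0.680 in ColGFP (log2 fold change 4.87 ± 0.75, adjusted p = 0.000554). The interferon-induced genes Ido1 and Tgtp1 were higher at 5.93 ± 1.95 and 4.52 ± 1.26. In TDonly replicate 1 Ido1 was at 39.6 CPM against 1.56 and 1.71 in replicates 2 and 3, and Tgtp1 at 59.6 against 9.37 and 8.44. Without TDonly replicate 1 the log2 fold change of Ido1 was 2.81 (adjusted p = 0.175), and it missed the threshold without TDonly replicate 1 or ColGFP replicate 1, 2 or 3 (adjusted p 0.0660 to 0.175). Tgtp1 did so without ColGFP replicate 2 or 3 (adjusted p 0.0581 to 0.0597), and by limma-voom neither passed (adjusted p = 0.274 and 0.124). The largest lower values included those of Hhip, Pappa2, Aspn, Kcnma1, Cacna2d3 and P4ha3. Hhip measured 22.6 ± 12.7 CPM in TDonly and 2275 ± 611 in ColGFP (log2 fold change -6.66 ± 0.54, adjusted p = 9.42e-06), the metalloproteinase Pappa2 1.75 ± 0.858 CPM in TDonly and 132 ± 47.7 in ColGFP (log2 fold change -6.25 ± 0.45, adjusted p = 5.18e-06) and the matrix proteoglycan Aspn 6.90 ± 3.76 CPM in TDonly and 369 ± 180.4 in ColGFP (log2 fold change -5.74 ± 0.58, adjusted p = 3.44e-05). The ion channel genes Kcnma1 and Cacna2d3 were lower at -5.46 ± 0.49 and -5.22 ± 0.28.

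Between TDonly and ColGFP 7082 genes differed, 3355 higher and 3727 lower in TDonly, with 1785 and 2208 of them at least 2-fold higher and lower. An unadjusted p under 0.05 was met by 8208 genes, and 56.1% of genes had no overlap (chance 10%). Camera called 16 of 36 lists with the preset correlation and 0 with an estimated one, where 5 had an unadjusted p under 0.05; fry called 25. Scaling by library totals alone moved the median log2 fold change of all genes by 0.15 and the share of differing genes that were higher from 47.4% to 59.3%.

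Some genes lay outside the range of both single-reporter populations in DBL, a level no mixture of them can give. Higher in DBL than in both were 135 genes. Aldh1a2, an enzyme that makes retinoic acid, measured 129.8 ± 16.6 CPM in DBL, 29.6 ± 16.9 in ColGFP and 24.1 ± 13.9 in TDonly, and the related Aldh1a3 58.0 ± 9.10 CPM in DBL, 15.7 ± 8.28 in ColGFP and 4.93 ± 2.82 in TDonly. The cytochrome P450 Cyp1b1 measured 197 ± 30.5 CPM in DBL, 46.4 ± 25.5 in ColGFP and 19.8 ± 3.94 in TDonly, with log2 fold changes of 2.09 ± 0.41 against ColGFP and 3.31 ± 0.43 against TDonly. Shisa3 and the lubricin gene Prg4 were higher than in ColGFP by 2.13 ± 0.48 and 1.97 ± 0.47, and than in TDonly by 3.21 ± 0.51 and 3.06 ± 0.50. Cxcl13, Ccl11, the interferon-inducible Ifi205, Dlg2 and AW551984 completed the 10 highest, with log2 fold changes from 1.82 to 3.25 against ColGFP. By list, 6 of 9 mesothelium genes were higher than in both (Msln, Upk3b, Lrrn4, Gpm6a, Rspo1 and Bnc1), 6 of 25 chemokine genes and 4 of 21 adventitial genes (Ccl11, Igfbp4, Sfrp2 and Il33). Cyp1b1 and Shisa3 passed against ColGFP whichever library was left out. Against ColGFP, Aldh1a2 missed the threshold without DBL replicate 1, 3 or 4 or ColGFP replicate 1 or 3 (adjusted p 0.0513 to 0.0913), Aldh1a3 without DBL replicate 1, 3 or 4 or ColGFP replicate 1, 2 or 3 (adjusted p 0.0526 to 0.0896), Ccl11 without DBL replicate 1, 3 or 4, ColGFP replicate 2 or 3, or TDonly replicate 2 (adjusted p 0.0684 to 0.1001) and Ifi205 without DBL replicate 1, ColGFP replicate 1, 2 or 3, or TDonly replicate 2 or 3 (adjusted p 0.0591 to 0.130). Prg4 did so without ColGFP replicate 1, 2 or 3 (adjusted p 0.0519 to 0.0777), Dlg2 without DBL replicate 1, 3 or 4, ColGFP replicate 2 or 3, or TDonly replicate 2 (adjusted p 0.0596 to 0.101) and AW551984 without DBL replicate 3 or 4 or ColGFP replicate 3 (adjusted p 0.0753 to 0.0766). Cxcl13 rested on DBL replicate 1, with 0.92 against ColGFP without it (adjusted p = 0.0547).

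Lower in DBL than in both were 32 genes. The kinase Prkcq measured 7.07 ± 0.224 CPM in DBL, 16.1 ± 3.05 in ColGFP and 13.97 ± 2.47 in TDonly, carbonic anhydrase Car2 35.9 ± 3.66 CPM in DBL, 59.0 ± 3.09 in ColGFP and 61.4 ± 10.4 in TDonly and the Notch target Hes1 49.7 ± 8.55 CPM in DBL, 76.9 ± 8.41 in ColGFP and 76.4 ± 3.87 in TDonly. D8Ertd82e (now Prag1) changed by -2.03 ± 0.13 against ColGFP and -0.83 ± 0.13 against TDonly, and the collagen galactosyltransferase Glt25d2 (now Colgalt2) by -0.65 ± 0.10 and -0.81 ± 0.10. Elmo1, Ogfrl1, Ncald, Mtss1 and Sipa1l2 were lower, at -0.53 to -1.02 against ColGFP. Hes1 missed the threshold against ColGFP without ColGFP replicate 2 (adjusted p = 0.0544), and Ogfrl1 against TDonly without DBL replicate 1 or 4 or TDonly replicate 3 (adjusted p 0.0502 to 0.0694). Gene lists of these sizes drawn independently would share 216.4 higher and 127.1 lower genes. In 20 simulations with no difference from either population no gene was outside the range, and in 20 simulated mixtures with 30% TDonly at most 4 were higher and 9 lower. Neither simulated a shift of the replicate 1 libraries. The higher count was 79 and 77 without DBL replicates 3 and 4 and 78 and 66 without ColGFP replicates 2 and 3, and the lower count 17 without DBL replicate 4. Against a log2 fold change of 1 (edgeR's glmTreat), 0 genes were higher and 0 lower than both (68 and 3 at an unadjusted p under 0.05). At 10 CPM or more the higher count was 86, and by DESeq2 the lower was 51. With the core number series as a covariate the counts were 286 and 80, with sets of neighbouring core numbers 233 and 61, and within the second series 404 and 108.

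**Figure D3:**
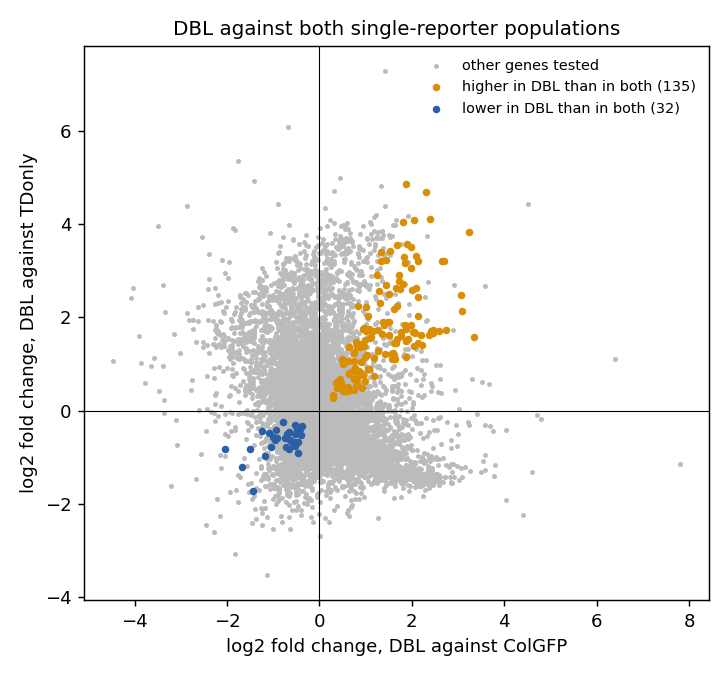
Log2 fold change of each tested gene in DBL against ColGFP (x axis) and against TDonly (y axis), 1 point per gene. Orange points are the 135 genes higher in DBL than in both populations, blue points the 32 lower than in both, and grey points all other genes tested.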

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

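The fit to the second series alone was chosen after the data were seen; the other alternatives were planned. Counts of differing, higher and lower genes stayed within 1.5 times the reported counts except where given here. Against a log2 fold change of 1 (glmTreat), 309 genes differed between DBL and ColGFP (229 higher, 80 lower), 951 between DBL and TDonly (840 and 111) and 2381 between TDonly and ColGFP (946 and 1435), as that test asks for larger changes; 0 genes were then higher and 0 lower in DBL than in both populations, with 68 and 3 at an unadjusted p under 0.05. For the other values the cause was not tested. DESeq2 gave 51 genes lower than both, and a filter of 10 CPM, which tests fewer genes, 86 higher than both. With the replicate number as a block 626 genes were lower in DBL than in ColGFP. The core number series as a covariate gave 286 genes higher and 80 lower than both, and sets of neighbouring core numbers gave 233 and 61. Within the second series 4512 genes differed between DBL and ColGFP (2543 higher, 1969 lower), 3031 were lower in DBL than in TDonly, and 404 were higher and 108 lower than both. Camera with an estimated correlation called 0 lists in each comparison (8, 5 and 5 at an unadjusted p under 0.05), and fry called 16, 24 and 25.

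With each library left out in turn, 1468 to 2761 genes differed between DBL and ColGFP (845 to 1488 higher, 581 to 1298 lower), 3479 to 5117 between DBL and TDonly (2264 to 3098 higher, 1155 to 2019 lower) and 5702 to 7361 between TDonly and ColGFP (2439 to 3465 higher, 3263 to 3938 lower). Between 66 and 182 genes were then higher and 17 to 44 lower in DBL than in both. Every fit without a library has fewer samples. Over 463 results for named genes and 23 alternatives, 10091 of 10586 values kept direction and side of the threshold. Another 493 no longer passed (187 with glmTreat), 2 newly passed and none reversed. Except sort genes, these were named for passing or a low adjusted p, which favours agreement. Residuals of libraries of different populations correlated across genes at 0.0143 to 0.527 within a core number series and at -0.424 to -0.0225 across series. The main model leaves out this structure. In the second series shared replicate numbers gave a mixed order. DBL replicate 3 had 0.232 with TDonly replicate 3 and 0.306 with TDonly replicate 2, but ColGFP replicate 3 had 0.0792 and 0.0254. Sets of neighbouring core numbers did so too. DBL replicate 4 had 0.340 with TDonly within its set and 0.289 across, but ColGFP replicate 2 had 0.0450 and 0.0489. Genes are not independent replicates. The model recovered 73% of simulated 2-fold changes, so smaller differences can be missed.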

Other observations

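All tests of explanations below were chosen after the patterns had been seen, except the splits and regroupings of libraries, which were planned. Lists of cell types and matrix not yet described had the following counts over all genes. Of 13 large vessel endothelium genes, there were 9 higher and 2 lower in DBL against ColGFP, 2 higher and 7 lower in DBL against TDonly and 8 higher and 3 lower in TDonly against ColGFP (9 and 3, 2 and 7, and 9 and 3 adjusted over the list alone). For large vessel endothelium genes camera gave adjusted p = 0.000313, 0.0314 and 0.00748 in that order (0.219, 0.433 and 0.351 with an estimated correlation). Of 8 lymphatic endothelium genes measured, there were 2 higher and 1 lower in DBL against ColGFP, 2 higher and 5 lower in DBL against TDonly and 5 higher and 2 lower in TDonly against ColGFP (3 and 1, 3 and 5, and 5 and 2 adjusted over the list alone). For lymphatic endothelium genes camera gave adjusted p = 0.395, 0.389 and 0.303 in that order. Of 16 pericyte genes, there were 3 higher and 1 lower in DBL against ColGFP, 8 higher and 1 lower in DBL against TDonly and 4 higher and 9 lower in TDonly against ColGFP (6 and 2, 9 and 1, and 4 and 9 adjusted over the list alone). For pericyte genes camera gave adjusted p = 0.0617, 0.0122 (adjusted p = 0.445 with an estimated correlation) and 0.330 in that order. The higher pericyte count in DBL against ColGFP was 5 without TDonly replicate 1. Of 17 basement membrane genes, there were 1 higher and 2 lower in DBL against ColGFP, 10 higher and 1 lower in DBL against TDonly and 6 higher and 10 lower in TDonly against ColGFP (3 and 2, 10 and 1, and 6 and 10 adjusted over the list alone). For basement membrane genes camera gave adjusted p = 0.449, 0.00221 (adjusted p = 0.309 with an estimated correlation) and 0.175 in that order. The higher basement membrane count in DBL against ColGFP was 3 without TDonly replicate 1, and 5 without ColGFP replicate 1. The higher basement membrane count in TDonly against ColGFP was 2 without ColGFP replicate 2 or 3. Of 18 matrix protease and inhibitor genes, there were 2 higher and 3 lower in DBL against ColGFP, 13 higher and 0 lower in DBL against TDonly and 2 higher and 14 lower in TDonly against ColGFP (3 and 4, 13 and 0, and 2 and 15 adjusted over the list alone). For protease and inhibitor genes camera gave adjusted p = 0.395, 1.12e-05 and 0.000213 in that order (0.315 and 0.351 for the last 2 with an estimated correlation). The higher protease and inhibitor count in DBL against ColGFP was 0 without DBL replicate 1 or ColGFP replicate 3, and 1 without ColGFP replicate 1 or 2 or TDonly replicate 2 or 3. The lower protease and inhibitor count in DBL against ColGFP was 0 without DBL replicate 3, and 1 without DBL replicate 1 or 4 or ColGFP replicate 2 or 3. Of 17 integrin genes, there were 7 higher and 4 lower in DBL against ColGFP, 6 higher and 5 lower in DBL against TDonly and 7 higher and 6 lower in TDonly against ColGFP (7 and 4, 6 and 5, and 7 and 6 adjusted over the list alone). For integrin genes camera gave adjusted p = 0.156, 0.768 and 0.452 in that order. The lower integrin count in DBL against ColGFP was 2 without DBL replicate 1 or 4 or ColGFP replicate 2 or 3. Of 15 stromal cell surface markers, there were 5 higher and 3 lower in DBL against ColGFP, 5 higher and 3 lower in DBL against TDonly and 4 higher and 6 lower in TDonly against ColGFP (6 and 4, 6 and 3, and 4 and 6 adjusted over the list alone). For stromal surface marker genes camera gave adjusted p = 0.449, 0.573 and 0.804 in that order. The lower stromal surface marker count in DBL against ColGFP was 1 without DBL replicate 4, and 5 without TDonly replicate 1. The higher stromal surface marker count in DBL against TDonly was 3 without TDonly replicate 3. Of 9 Schwann cell and neuron genes, there were 2 higher and 0 lower in DBL against ColGFP, 1 higher and 0 lower in DBL against TDonly and 4 higher and 1 lower in TDonly against ColGFP (6 and 0, 0 and 0, and 4 and 1 adjusted over the list alone). For Schwann and neuron genes camera gave adjusted p = 0.00689 (adjusted p = 0.326 with an estimated correlation), 0.580 and 0.203 in that order. The higher Schwann and neuron count in DBL against ColGFP was 1 without DBL replicate 4, and 6 without TDonly replicate 1. The higher Schwann and neuron count in TDonly against ColGFP was 2 without ColGFP replicate 2 or TDonly replicate 2. Of 5 chondrocyte genes, there were 0 higher and 0 lower in DBL against ColGFP, 2 higher and 0 lower in DBL against TDonly and 0 higher and 4 lower in TDonly against ColGFP (0 and 0, 3 and 0, and 0 and 4 adjusted over the list alone). For chondrocyte genes camera gave adjusted p = 0.395, 0.0670 and 0.0602 in that order. Of 10 erythroid and platelet genes, there were 0 higher and 0 lower in DBL against ColGFP, 0 higher and 1 lower in DBL against TDonly and 4 higher and 0 lower in TDonly against ColGFP (0 and 0, 0 and 0, and 4 and 0 adjusted over the list alone). For erythroid and platelet genes camera gave adjusted p = 0.859, 0.117 and 0.282 in that order. In DBL against ColGFP, by edgeR at an unadjusted p under 0.05, 2 chondrocyte genes were lower and 1 erythroid and platelet gene higher.

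Signalling, metabolic and other lists had the following counts. Of 17 genes of lysophosphatidic acid signalling and NFAT, there were 2 higher and 2 lower in DBL against ColGFP, 8 higher and 4 lower in DBL against TDonly and 5 higher and 9 lower in TDonly against ColGFP (2 and 2, 8 and 4, and 5 and 9 adjusted over the list alone). For these signalling genes camera gave adjusted p = 0.610, 0.164 and 0.160 in that order. Of 18 complement and interferon genes, there were 2 higher and 0 lower in DBL against ColGFP, 8 higher and 0 lower in DBL against TDonly and 4 higher and 8 lower in TDonly against ColGFP (2 and 0, 8 and 0, and 4 and 8 adjusted over the list alone). For complement and interferon response genes camera gave adjusted p = 0.0120, 0.00769 and 0.378 in that order (0.637 and 0.445 for the first 2 with an estimated correlation). The lower complement and interferon response count in DBL against TDonly was 3 without DBL replicate 1. The higher complement and interferon response count in TDonly against ColGFP was 2 without TDonly replicate 1 or ColGFP replicate 1, 2 or 3, and 8 without DBL replicate 1. Of 14 retinoid genes, there were 3 higher and 2 lower in DBL against ColGFP, 5 higher and 2 lower in DBL against TDonly and 2 higher and 5 lower in TDonly against ColGFP (3 and 3, 5 and 2, and 2 and 5 adjusted over the list alone). For retinoid metabolism genes camera gave adjusted p = 0.395, 0.121 and 0.378 in that order. The higher retinoid metabolism count in DBL against ColGFP was 1 without DBL replicate 1, 3 or 4 or ColGFP replicate 1 or 3. The lower retinoid metabolism count in DBL against ColGFP was 0 without DBL replicate 1, 3 or 4 or ColGFP replicate 2 or 3, 1 without ColGFP replicate 1, and 4 without TDonly replicate 1. Of 19 lipid handling genes, there were 2 higher and 2 lower in DBL against ColGFP, 4 higher and 2 lower in DBL against TDonly and 5 higher and 6 lower in TDonly against ColGFP (4 and 3, 4 and 2, and 6 and 6 adjusted over the list alone). For lipid handling genes camera gave adjusted p = 0.859, 0.931 and 0.790 in that order. The lower lipid handling count in DBL against ColGFP was 0 without DBL replicate 3 or 4 or ColGFP replicate 2 or 3, and 1 without DBL replicate 1 or TDonly replicate 2 or 3. The higher lipid handling count in DBL against TDonly was 2 without DBL replicate 3 or TDonly replicate 3. The lower lipid handling count in DBL against TDonly was 1 without DBL replicate 3 or 4, and 4 without DBL replicate 1 or ColGFP replicate 1. The higher lipid handling count in TDonly against ColGFP was 3 without TDonly replicate 2 or 3. Of 22 cell cycle genes, there were 2 higher and 0 lower in DBL against ColGFP, 0 higher and 2 lower in DBL against TDonly and 11 higher and 1 lower in TDonly against ColGFP (2 and 0, 0 and 2, and 12 and 1 adjusted over the list alone). For cell cycle genes camera gave adjusted p = 0.0229, 0.0887 and 0.0111 in that order (0.683 and 0.557 for the first and last with an estimated correlation). The lower cell cycle count in DBL against TDonly was 5 without DBL replicate 1. The higher count in TDonly against ColGFP was 4, 4 and 3 without TDonly replicate 1, ColGFP replicate 2 and ColGFP replicate 3. Of 11 housekeeping genes, there were 0 higher and 0 lower in DBL against ColGFP, 0 higher and 0 lower in DBL against TDonly and 3 higher and 0 lower in TDonly against ColGFP (0 and 0, 0 and 0, and 1 and 0 adjusted over the list alone). For housekeeping genes camera gave adjusted p = 0.732, 0.245 and 0.295 in that order. The higher housekeeping count in TDonly against ColGFP was 1 without TDonly replicate 1 or 3 or ColGFP replicate 2 or 3. At an unadjusted p under 0.05 by edgeR, 1 housekeeping gene was higher in DBL against ColGFP and 1 lower in DBL against TDonly. In DBL against TDonly, BMP genes numbered 14 higher and 7 lower (14 and 7 adjusted over the list alone), VEGF and Notch genes 9 higher and 11 lower (9 and 11 adjusted over the list alone) and forkhead genes 5 higher and 3 lower (5 and 3 adjusted over the list alone), with camera adjusted p = 0.201, 0.573 and 0.705. Fibrillar collagen genes in DBL against ColGFP numbered 1 higher and 3 lower (1 and 3 adjusted over the list alone) and other matrix genes 1 higher and 2 lower (3 and 3 adjusted over the list alone) (camera adjusted p = 0.395 and 0.109). The lower fibrillar collagen count was 5 without TDonly replicate 1. The lower count of other matrix genes was 11 without TDonly replicate 1. Its higher count was 0 without ColGFP replicate 2, 2 without ColGFP replicate 1, and 3 without TDonly replicate 1. In TDonly against ColGFP the lower forkhead count was 5 without ColGFP replicate 1. In TDonly against ColGFP chemokine genes numbered 3 higher and 10 lower (4 and 10 adjusted over the list alone) (camera adjusted p = 0.362). Only 1 posterior Hox gene was measured, Hoxb8, lower in TDonly than in ColGFP at -2.28 ± 0.62 but not without ColGFP replicate 3 (adjusted p = 0.0549). In the second series alone these other counts moved over 1.5-fold, by 2 genes or more. In DBL against ColGFP they were hedgehog 3 higher and 7 lower, pericyte 7 higher, erythroid 2 lower, Schwann and neuron 7 higher, chondrocyte 3 lower, fibrillar collagen 4 higher and 7 lower, other matrix 5 higher and 15 lower, basement membrane 9 higher and 4 lower, protease 5 higher and 10 lower, stromal marker 6 lower, FGF and HGF 3 higher, lysophosphatidic acid 4 lower, chemokine 3 lower, complement 6 higher and 2 lower, lipid 6 higher and 5 lower, retinoid 4 lower, housekeeping 2 higher. In DBL against TDonly they were alveolar fibroblast 3 lower, large vessel 4 higher, erythroid 6 lower, chondrocyte 4 higher, basement membrane 5 lower, protease 2 lower, stromal marker 5 lower, FGF and HGF 6 lower, chemokine 5 lower, complement 4 lower, cell cycle 5 lower, lipid 9 lower, retinoid 9 higher, housekeeping 3 lower, and in TDonly against ColGFP forkhead 5 lower, FGF and HGF 5 higher, chemokine 6 higher, complement 8 higher, lipid 9 higher, housekeeping 5 higher. The median, the mean and the direction by camera differed in sign in DBL against ColGFP for erythroid and platelet, fibrillar collagen and crosslinking, lipid handling; in DBL against TDonly for integrin, VEGF, angiopoietin and Notch pathway, lipid handling; in TDonly against ColGFP for FOXF1 locus and forkhead partners, mesothelium, mesenchymal stromal cell surface markers, VEGF, angiopoietin and Notch pathway. Meg3, Rian and Rtl1, imprinted transcripts of the Dlk1-Dio3 locus named after their values were seen, were higher in DBL than in both populations. Meg3 was 87.5 ± 33.6, 208 ± 10.5 and 27.9 ± 6.32 CPM, with log2 1.251 against ColGFP (adjusted p = 0.0151) and 2.90 ± 0.30 against TDonly. Rian and Rtl1 were at 1.33 ± 0.32 and 1.52 ± 0.35 against ColGFP; Rian missed the threshold without DBL replicate 3 or 4 or ColGFP replicate 3 (adjusted p 0.0554 to 0.0730) and Rtl1 without DBL replicate 3 or 4 (adjusted p 0.0501 to 0.0610). Dlk1, Mirg and Dio3 did not pass against ColGFP (adjusted p = 0.253, 0.0758 and 0.128).

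The first pattern is endothelial transcripts and Foxf1 at an intermediate level in DBL, with alveolar fibroblast and smooth muscle transcripts below ColGFP. Free RNA from lysed lung cells stays open as a source. Median DBL over ColGFP ratios were 1.05 for 6 type II cell transcripts and 5.41 for the endothelium list. Without the replicate 1 libraries they were 1.67 and 5.84, so type II transcripts also rose. Cells or RNA of the TDonly kind in the DBL libraries, such as doublets or a wide gate, may account for the endothelial part. The list gave a median share of 29.3% (25.7 to 32.8% over its genes, and 34.7, 26.2 and 24.98% in the DBL libraries). At 10 CPM or more, 499 other genes at least 4-fold higher in TDonly lay at a median of 1.02 times the level that share predicts, 94.6% within 1.5-fold. For 725 genes at least 4-fold higher in ColGFP these were 0.827 and 48.3%. Foxf1 alone gave a share of 21.5% and Fendrr 37.2%, below and above the range of the endothelial genes, although Foxf1 at 100.5 CPM (SD 13.1) was within 1.5-fold of the 116.2 predicted. That share does not account for the alveolar fibroblast genes, whose 16 members lower in TDonly lay at a median of 0.459 times the predicted level (interquartile range 0.423 to 0.555; 0.479 in the second series), but it stays open for 17 smooth muscle genes: at 0.671 (0.512 to 0.779; in the second series 0.756, 0.508 to 1.02) they lay below the interquartile range of all 2770 genes higher in ColGFP at 10 CPM or more (0.7997 to 1.09) and within that of the 725 at least 4-fold higher (0.576 to 1.21). A different mix or state of collagen reporter cells, and expression of endothelial genes and Foxf1 by the DBL cells themselves, the biological reading that the sort names, were not tested and stay open.

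The second pattern is the 135 genes higher in DBL than in both other populations. A mixture of the single-reporter populations cannot exceed both sources, which argues against it as the genes' whole source only if chance is excluded. At most 4 such genes appeared in 20 simulated mixtures, which held no shift of the replicate 1 libraries. Whether chance assignment of the libraries can be excluded stays open: 1 of 100 regroupings, the real one, gave as many as 167 genes outside the range (highest other 0 by edgeR), but other regroupings put the differences between populations into the residual, which keeps their counts low, and at an unadjusted p under 0.05, 6 of the 100 gave as many as the real grouping (457; highest other 756). Mesothelial cells in the DBL gate may account for the mesothelial part, but that 6 of 9 markers were higher than in both only prompted this explanation and does not test it. Msln was at 241 ± 32.2, 43.9 ± 7.56 and 75.6 ± 41.8 CPM in DBL, ColGFP and TDonly, whereas Upk1b, at 70.0 ± 5.42, 112 ± 16.7 and 21.1 ± 11.2, was not highest in DBL; expression by the DBL cells themselves stays open for all these genes.

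The third pattern is surfactant RNA in all 3 populations, although neither reporter is known for type II cells. Sftpc was 4496 ± 2351 CPM in ColGFP, 4632 ± 60.5 in DBL and 7642 ± 746 in TDonly (SD, n = 3). RNA of alveolar type II cells from a common source, as cells or free RNA, may account for it: the TDonly over ColGFP ratios of 6 type II transcripts on CPM of library totals were 1.77 to 1.96, the highest 1.11 times the lowest, while the airway gene Scgb1a1 had 7.65 and macrophage Chi3l3 4.03. The size of the 6 ratios depends on the replicate 1 libraries: in the second series they were 2.97 to 3.32, the highest 1.12 times the lowest. The test cannot separate captured cells from free RNA, and no biological explanation was tested.

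Each pair of populations can be split into 2 groups of 3 in 10 ways, too few for a share under 0.05. For differing genes, 1 of the 10 splits, the real one, gave as many in DBL against ColGFP (2256; highest other 0), 1 in DBL against TDonly (4657; highest other 0) and 1 in TDonly against ColGFP (7082; highest other 0). By edgeR at an unadjusted p under 0.05 these were 4186 against 979, 6331 against 1073 and 8208 against 945. For lists called by camera, 1 of the 10 gave as many in DBL against ColGFP (18; highest other 13), 1 in DBL against TDonly (22; highest other 20) and 3 in TDonly against ColGFP (16; highest other 17).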
